A study of Methanobrevibacter ruminantium with 9 samples.

How the data were processed

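RNA was sequenced from 9 bottles of a pure culture of Methanobrevibacter ruminantium M1, a hydrogen-using methane-forming archaeon of the rumen. Per the labels' protocols, all bottles were inoculated from the same growing culture, held 50 mL of medium and were kept at 39 °C under carbon dioxide and hydrogen. After 60 h, 3 bottles received lauric acid dissolved in dimethyl sulfoxide (DMSO), 3 received DMSO alone and 3 received nothing, and cells were collected 1 h later. Groups were taken from the supplement stated for each sample, and the replicate numbers 1 to 9 from the sample titles. The bottles were separate cultures, but they came from a single inoculum, so the errors given here rest on bottles of 1 experiment only.

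The authors deposited 1 table per library with the raw count of reads for each of 2283 features, per the file headers. The aligner, the counting tool, the genome build, the annotation and the handling of strand and of reads that match several places are not given in the sources used here. Genes that have a numbered copy in the tables, such as mtrA1 and mtrA2 or rbr2, can share reads with that copy, and their values are uncertain to that extent. The table of no-supplement replicate 1 ended with 2 entries that carried no feature name. One of them equalled the sum of all named features, and the other held a value of unstated meaning that was not whole. Both were left out, and no other table held such entries.

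Of the 2283 features, 634 carried a gene symbol and 1649 only a locus ID, which the files do not pair with names. No annotation was used here. Ribosomal and transfer RNA genes could therefore not be told from other features, and their planned removal was not made. The counts summed to between 14458627 and 27542936 reads per library. Intervals of counting error were not computed, and values are given as group means with their standard deviation (SD).

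Counts were analysed in R 4.3.3 with edgeR 4.0.16. Features were kept by edgeR's expression filter with the groups as design, which left 2238 features for testing and removed 45. Library sizes were scaled by trimmed-mean (TMM) factors. A quasi-likelihood model with 1 coefficient per group was fitted to all 9 libraries, and each contrast was tested by the quasi-likelihood F-test, which is two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. All adjusted p of single genes in the text come from this edgeR fit unless another tool or fit is named. The standard error (SE) of a log2 fold change was its size divided by the square root of F. Levels are CPM values, that is counts relative to the library size after TMM scaling. No covariate was used, and no number in the labels pairs cultures of different groups.

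Gene groups were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, over lists with at least 3 tested members, with Benjamini-Hochberg adjustment over the lists. Camera asks whether the genes of a list rank higher or lower than the other genes. Each list test was repeated with a correlation estimated from the data. Of 33 lists fixed beforehand, 20 could be tested and 9 matched no feature, because most features carry a locus ID only. The lists were written as patterns of gene symbols. Symbols that a pattern took in by mistake, such as histidine synthesis genes taken for histones and aminoacyl-tRNA synthetase genes taken for amino acid synthesis, were removed after the symbols were seen. A further 14 narrower lists were written after the results had been seen, and they are used only among the other observations.

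The comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. For lauric acid against the DMSO control, the rule took the 8 largest rises and the 8 largest falls among called genes with a mean of at least 50 counts whose 3 values did not overlap between the groups. It also took up to 2 called members per list and direction, and a fixed set of genes of methane formation, ATP synthesis, cell division, protein folding and the prophage lysis enzyme peiR. For the other 2 comparisons it took the 5 largest rises and falls and the fixed set. The fixed names mtrA, ftr and atpA were matched to mtrA1 and mtrA2, ftr1 and ftr2, and ahaA. Of the many locus IDs that the rule took, 2 that rose and 2 that fell are printed. The genes hypC, nikA1, trpE and trpB2 in the first comparison, and in the others the examples given for the gene lists and the genes followed across comparisons, were chosen after their values were seen.

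The procedure was tested on counts simulated for the 2238 genes in the comparison of lauric acid with the DMSO control, with 200 genes changed in each of 10 runs. With the same spread in all groups, it recovered 19.0% of genes changed by 0.5 on the log2 scale, 77.5% of those changed by 1 and 96.5% of those changed by 2, and 4.78% of its calls were false. With each group given its own observed spread, set to 1 value for all genes, it recovered 24.3%, 66.8% and 99.8%. Of its calls 31.5% were then false. In a second simulation with unequal spread, 29.1% of calls were false with edgeR on all 9 libraries, 4.41% with edgeR on the 6 libraries compared, 29.7% with limma voom, 8.46% with limma voom and a weight per group, and 50.8% with DESeq2 1.42.0. At an unadjusted p under 0.05, camera found 20 of 20 simulated lists of 30 genes shifted by 0.5, and 2 of 20 unshifted lists. These lists were simulated with the same spread in all groups. Genes were drawn independently of each other, so lists of correlated genes were not covered.

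The alternatives were other scalings (relative log expression, upper quartile, library totals, and the median log ratio of abundant genes), no filter and a filter at a mean of 50 counts, thinning of all libraries to the smallest, edgeR with robust estimation, DESeq2, limma voom, a fit to only the 6 libraries compared, stricter thresholds and leaving out each replicate in turn. A fit with weights per group and a fit without mru_2278 to mru_2285 were added after the data had been seen. The overlap of calls between comparisons was set beside the overlap of independent lists, and the correlation and covariance of fold changes beside 50 simulated draws without any effect.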

Results

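The transcriptome of Methanobrevibacter ruminantium M1 was measured by RNA sequencing on an Illumina HiSeq2500 in 9 cultures, 3 per group. Lauric acid, a saturated fatty acid that is studied as a feed additive against methane formation in ruminants, was added as 0.1 mL of a stock of 200 mg/mL in DMSO to a final 0.4 mg/mL. Per the labels, this dose was chosen to inhibit methane formation while most cells stayed alive. The DMSO control received 0.1 mL of the solvent, giving 0.2%, and the no-supplement group received nothing. The libraries held 23403573 to 27542936 counted reads without supplement, 24505009 to 26504352 in the DMSO control, and 20997915, 23635912 and 14458627 in lauric acid replicates 7, 8 and 9.

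A few features took a large share of the reads, and this share differed between the DMSO control and no supplement. The feature mru_2284 held 34.8% ± 8.10 (SD, n = 3) of the reads without supplement, 12.2% ± 2.97 in the DMSO control and 17.2% ± 15.7 with lauric acid. The 8 neighbouring IDs mru_2278 to mru_2285 together held 46.1% ± 10.6, 16.3% ± 3.81 and 23.1% ± 21.02. Lauric acid replicate 7 carried much of the lauric acid values, with shares of mru_2284 of 35.2%, 10.2% and 6.28% in replicates 7, 8 and 9 and of the 8 IDs of 47.2%, 13.5% and 8.61%. Without it the lauric acid means were 8.24% and 11.1%, lower than in the DMSO control. With library totals in place of TMM factors, the median log2 fold change of all genes moved to -0.21 for lauric acid against the DMSO control, to 0.58 for the DMSO control against no supplement and to 0.37 for lauric acid against no supplement. All changes below are relative to the bulk of the other genes, as TMM scaling sets it.

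**Figure D1:**
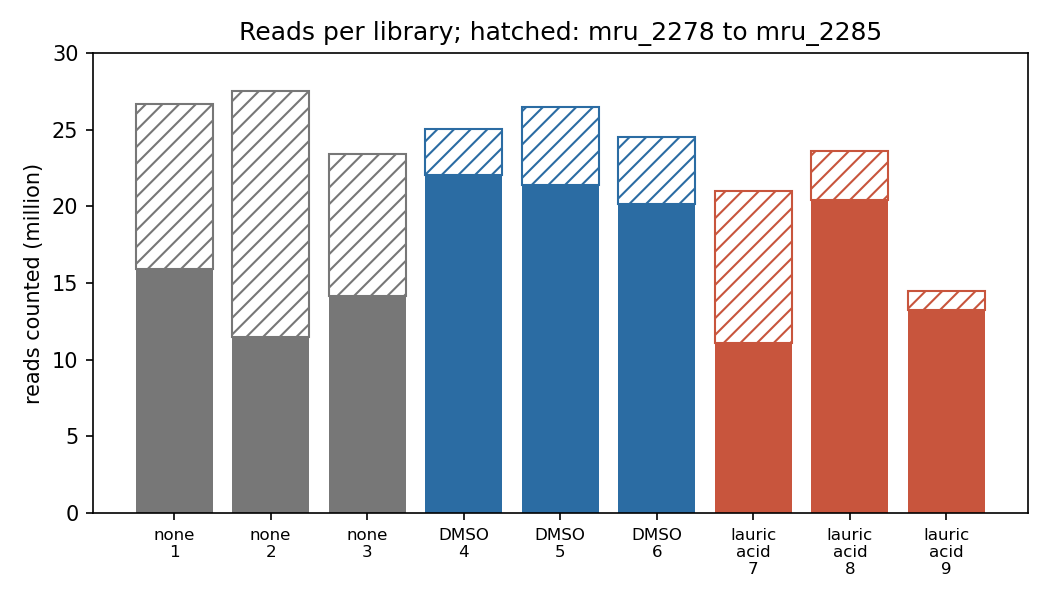
Reads counted per library, by group and replicate, with the hatched part of each bar showing the reads of mru_2278 to mru_2285. These features held 46.1% ± 10.6 (SD, n = 3) of the reads without supplement, 16.3% ± 3.81 in the DMSO control and 23.1% ± 21.02 with lauric acid, where replicate 7 alone had 47.2%.

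The lauric acid cultures differed from each other far more than the cultures of the other groups did. The biological coefficient of variation was 0.360 with lauric acid, 0.0357 in the DMSO control and 0.0623 without supplement. Chi-square per degree of freedom between pairs of replicates was 696 to 1049 with lauric acid, 5.00 to 10.3 in the DMSO control and 8.08 to 18.4 without supplement, so no pair agreed within sampling noise. On the first principal component, which held 55.0% of the variance of log2 CPM, lauric acid replicates 7 and 8 lay at 16.5 and 13.2 near the DMSO control at 11.1 to 11.4. Lauric acid replicate 9 lay at -18.5, on the side of the no-supplement cultures at -15.8 to -14.5, and it was set apart from all other cultures on the second component at -18.9. Replicates 7 and 8 were set apart too, at -6.23 and -14.8 on the third component, where the DMSO control lay at 7.63 to 8.39, and at -15.1 and 10.8 on the fourth. The root mean square log2 difference to the DMSO cultures was 0.511 to 0.542 for replicates 7 and 8, that of replicate 9 to the no-supplement cultures was 0.554 to 0.593, and DMSO cultures differed among themselves by 0.129 to 0.143.

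**Figure D2:**
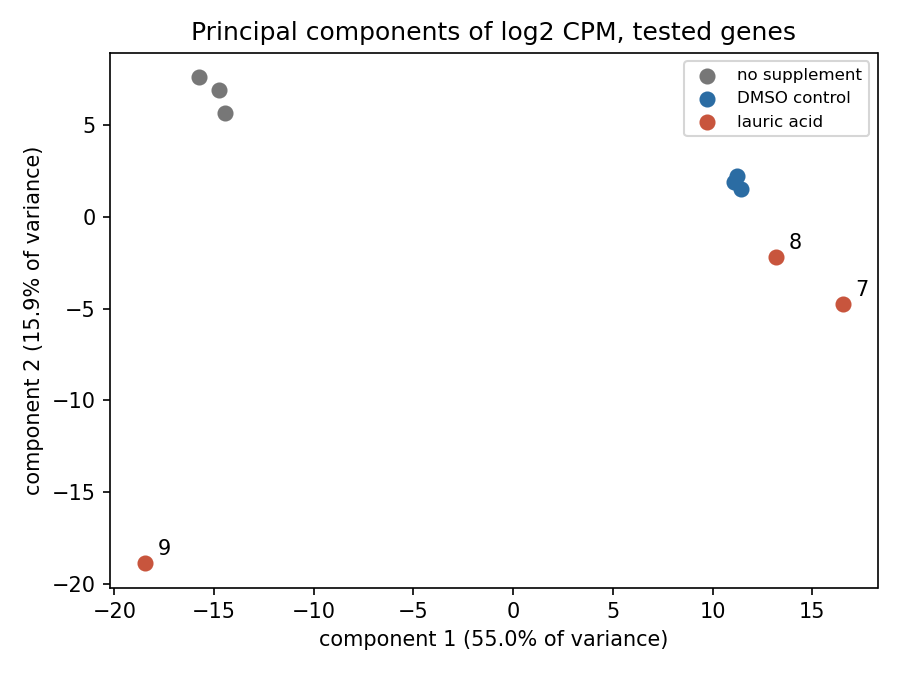
First and second principal components of log2 CPM over the tested genes, holding 55.0% and 15.9% of the variance, with 1 point per culture coloured by group and the lauric acid replicates numbered. On the first component lauric acid replicates 7 and 8 lie on the side of the DMSO control, at 16.5 and 13.2, and replicate 9 on the side of no supplement, at -18.5, while it lies at -18.9 on the second.

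The comparison of lauric acid with the DMSO control asked which genes respond to the fatty acid itself, since both groups received the solvent. The labels describe a single set of bottles. In each comparison, an effect of the supplement therefore cannot be told apart from bottles grown or handled as a group. The genes with the smallest adjusted p included nifB of nitrogenase cofactor synthesis, hypA and hypB of hydrogenase maturation and cbiN1 of cobalt transport. Of the 6 genes of nitrogen assimilation nifB alone was called, and that list was not called (camera adjusted p = 0.0623). The transcript of nifB, whose product builds the precursor of the nitrogenase cofactor, stood at 555 ± 61.4 CPM (SD, n = 3) with lauric acid and at 94.0 ± 4.29 in the DMSO control, a 5.90-fold rise (log2 2.56 ± 0.10 SE, adjusted p = 7.54e-06). The hydrogenase maturation genes hypA and hypB, which take part in the insertion of nickel, rose by log2 1.97 ± 0.12 and 2.05 ± 0.13 (adjusted p = 0.000133 for both), and hypC rose by 0.86 ± 0.08 (adjusted p = 0.00127). The cobalt transport genes cbiN1 and cbiM1 rose by 1.12 ± 0.08 and 0.94 ± 0.09 (adjusted p = 0.00022 and 0.00115). The rubrerythrin gene rbr2, which serves the removal of peroxide, rose 2.57-fold (log2 1.36 ± 0.14, adjusted p = 0.00166), with adjusted p = 0.0676 in the fit to the 6 libraries compared and 5.13e-30 to 0.191 over the 19 alternatives.

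**Figure D3:**
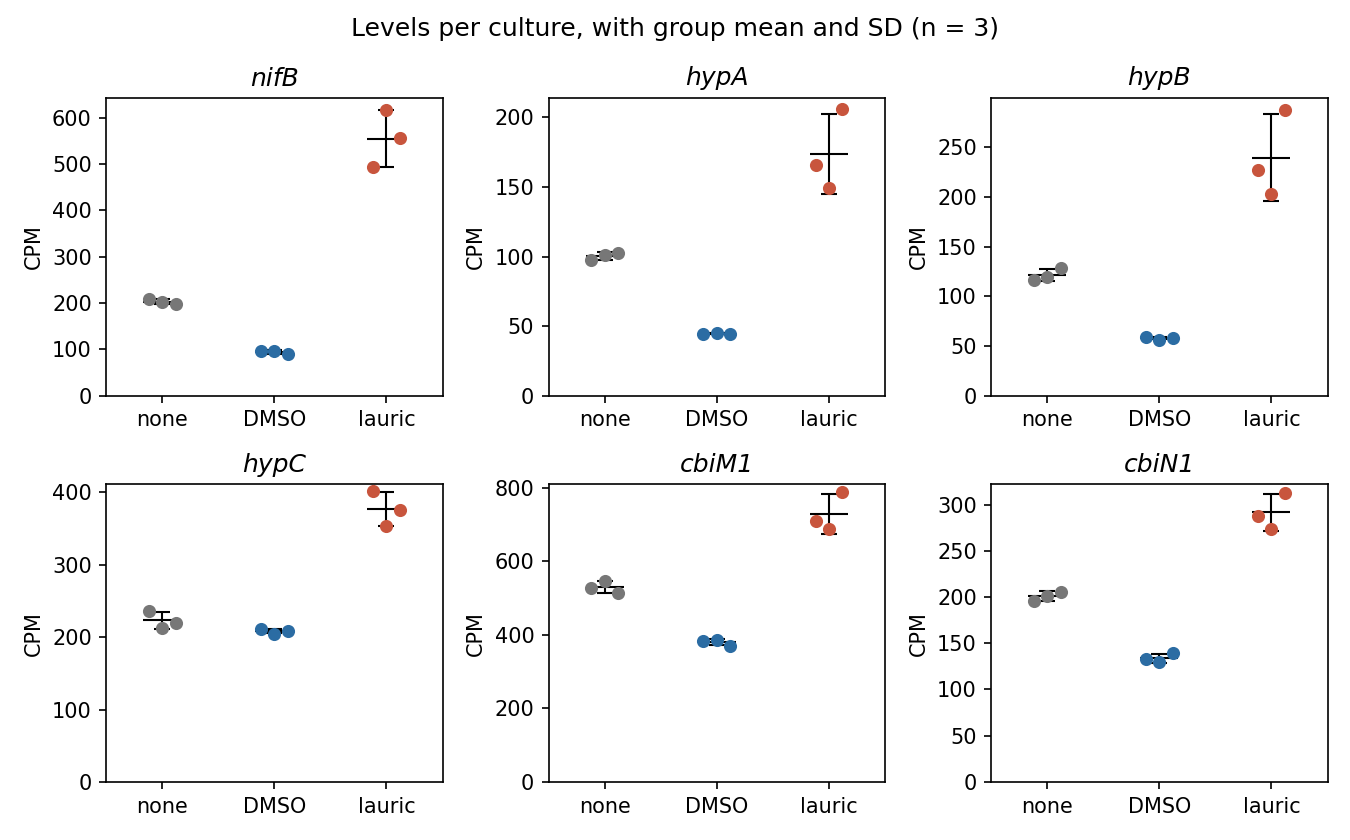
Levels in CPM of nifB, hypA, hypB, hypC, cbiM1 and cbiN1, with 1 point per culture, group means and SD (n = 3). All 3 lauric acid cultures lie above all 3 DMSO cultures for each gene, and nifB stood at 555 ± 61.4 CPM with lauric acid and at 94.0 ± 4.29 in the DMSO control.

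In all, 145 of 2238 genes were called, of which 98 rose and 47 fell, and 13 at least doubled while 4 at least halved. The split of calls moved to 67 higher and 76 lower with upper-quartile factors, to 64 and 67 with the median log ratio of abundant genes, and to 5 and 0 with library totals. The 3 values of each group did not overlap at 28.7% of genes. Chance gives 10% only where both groups have the same spread. With lauric acid cultures far more variable than DMSO cultures it gives more, by an amount not computed, so no conclusion is drawn from this share. The fit to only the 6 libraries compared, in which the spread is not shared with the no-supplement cultures, called 7 genes, all higher, which were nifB, hypA, hypB, hypC, cbiM1, cbiN1 and 1 feature with a locus ID only. Without DMSO replicate 4, 5 or 6 the count was 10, 9 and 9, and without lauric acid replicate 7, 8 or 9 it was 527, 286 and 656. In simulated counts with 1 spread per group for all genes, 31.5% of the calls of this comparison were false. The observed spread differed between genes, so this share does not carry over to the 145 genes. Of the 36 named genes called here, 6 kept their call in the fit to 6 libraries, 7 without DMSO replicate 4, 5 or 6 each and 5 with library totals.

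Several of the largest rises had a wide spread. The feature mru_0347 rose by log2 4.49 ± 0.98 (adjusted p = 0.0349), at 53.1, 80.4 and 780 CPM in lauric acid replicates 7, 8 and 9. It stood at 12.9 to 14.0 CPM in the DMSO control and at 74.4 to 87.1 CPM without supplement. The transcript of deoC, which encodes deoxyribose-phosphate aldolase, rose by 4.41 ± 0.58 (adjusted p = 0.0087), from 86.4 ± 0.865 CPM in the DMSO control to 766, 1029 and 3722 CPM in lauric acid replicates 7, 8 and 9. The gene fprA2, of the family of F420-dependent oxygen-reducing flavoproteins, rose by 2.66 ± 0.52 (adjusted p = 0.0247) and stood at 1932, 1760 and 7457 CPM. Without lauric acid replicate 9 the rises of mru_0347, deoC and fprA2 were 2.29, 3.37 and 1.64. Among the falls were tfb2, a transcription factor B gene, at -1.35 ± 0.30 (adjusted p = 0.0373), mru_0076 at -0.91 ± 0.11 (adjusted p = 0.00659), the enolase gene eno at -0.81 ± 0.17 (adjusted p = 0.0281) and the asparagine synthetase gene asnB at -0.73 ± 0.12 (adjusted p = 0.015). In the fit to 6 libraries the adjusted p of these genes lay between 0.0892 and 0.168.

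Of the 20 gene lists tested, camera called 7, all as higher with lauric acid than in the DMSO control. None of these 7 was called for lauric acid against no supplement, where 0 amino acid synthesis genes rose and 8 fell. The amino acid, aminoacyl-tRNA synthetase and purine lists were called as lower in the DMSO control than without supplement. In the edgeR fit to the 6 libraries of lauric acid and the DMSO control, 2 genes of metal ion transport and cobalamin rose. No gene of the other called lists was called in it. The examples given below for the called lists, other than cbiN1, cbiM1 and rbr2, had adjusted p of 0.119 to 0.202 in that fit. Relative to the DMSO control, 9 of 65 amino acid synthesis genes rose and 1 fell with lauric acid. Adjusted over the list alone 13 rose and 1 fell. Their examples were glyA at log2 0.67 ± 0.09, argG at 0.48 ± 0.07 and trpE at 0.45 ± 0.08, while asnB fell. The list had a camera adjusted p = 0.00338, and adjusted p = 0.386 with an estimated correlation. Of 33 purine and pyrimidine synthesis genes, 6 rose and 1 fell, with 7 and 2 adjusted over the list alone, among them the anaerobic ribonucleotide reductase gene nrdD at 1.13 ± 0.20, the thymidylate synthase gene thyA at 0.48 ± 0.08 and purL at -0.48 ± 0.07. Its camera adjusted p = 0.00644 became adjusted p = 0.156 with an estimated correlation. Of 51 genes of metal ion transport and cobalamin, 7 rose and 0 fell, with 11 and 0 adjusted over the list alone, led by cbiN1, cbiM1 and the nickel transport gene nikA1 at 0.67 ± 0.11. The camera adjusted p was 0.0439, and adjusted p = 0.386 with an estimated correlation.

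Of 16 aminoacyl-tRNA synthetase genes, pheS and proS rose, by 0.43 ± 0.07 and 0.31 ± 0.07, and 5 rose adjusted over the list alone. The camera adjusted p was 0.0178, and adjusted p = 0.386 with an estimated correlation. Of 9 genes of oxygen and redox defence, rbr2 and fprA2 rose, and 3 rose adjusted over the list alone, with a camera adjusted p = 0.0278 and adjusted p = 0.206 with an estimated correlation. Of 6 genes of isoprenoid and ether lipid synthesis, the mevalonate kinase gene mvk rose by 0.39 ± 0.08, and 4 rose adjusted over the list alone, with a camera adjusted p = 0.0219 and adjusted p = 0.206 with an estimated correlation. Of 5 chaperone and protein turnover genes none was called by edgeR, while 2 rose adjusted over the list alone, 2 were higher at an unadjusted p under 0.05 and 2 were called with DESeq2. That list had a camera adjusted p = 0.0355, and adjusted p = 0.399 with an estimated correlation. With library totals the list medians turned negative for amino acid synthesis at -0.06 and purine and pyrimidine synthesis at -0.06. They did so too for metal ion transport and cobalamin at -0.16 and oxygen and redox defence at -0.07. The median of all genes then stood at -0.21. The metal list also stood at -0.01 with upper-quartile factors and with the median log ratio of abundant genes.

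**Figure D4:**
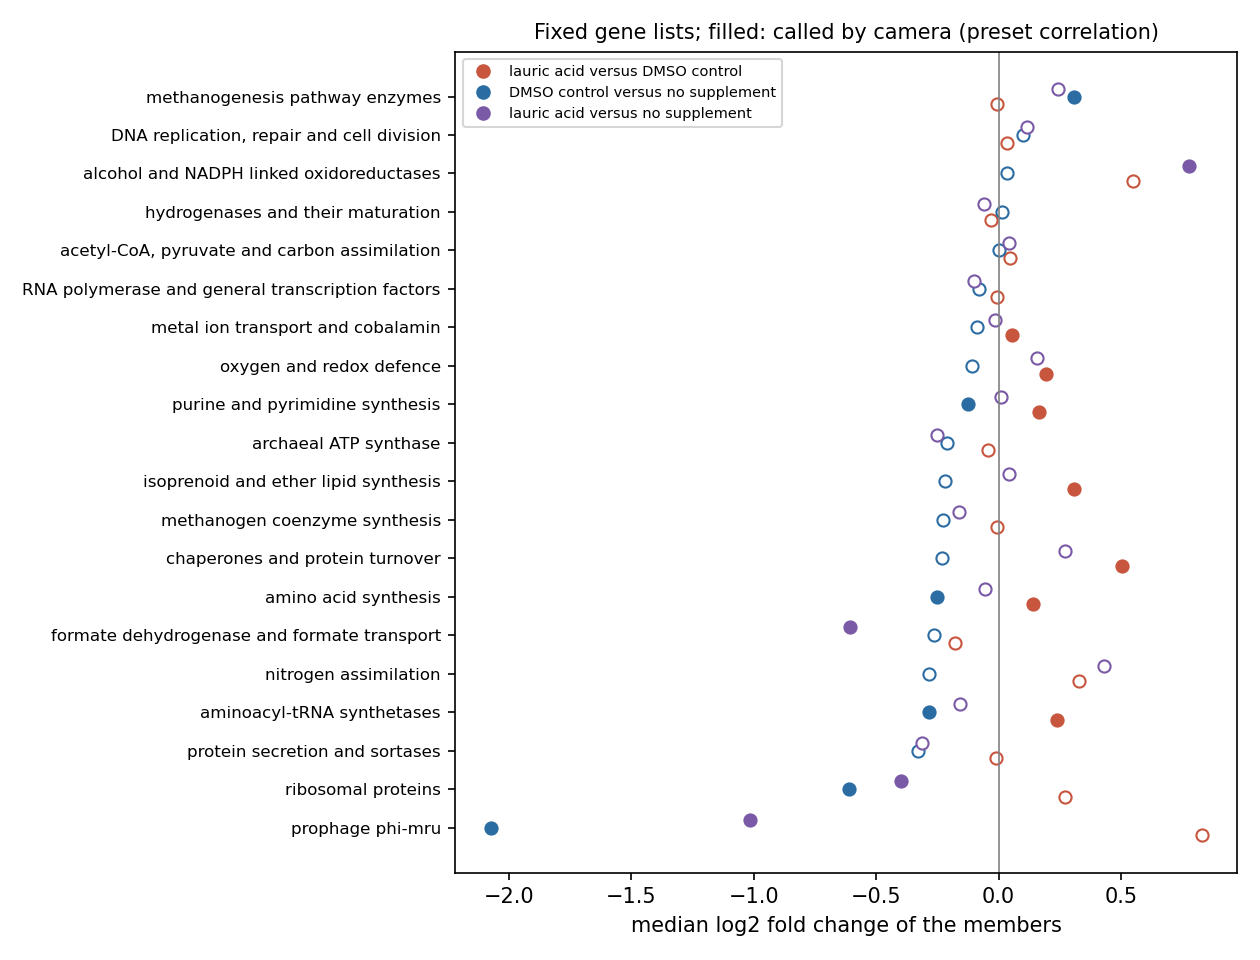
Median log2 fold change of the members of each of the 20 gene lists in the 3 comparisons, with filled points for lists called by camera with the preset correlation. The prophage list stood at 0.83, -2.07 and -1.02 for lauric acid against the DMSO control, the DMSO control against no supplement and lauric acid against no supplement; no call held with an estimated correlation, and with library totals some list medians change sign.

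The enzymes of methane formation were not called as a group. Of 34 genes, 1 rose and 0 fell, the same adjusted over the list alone, and the camera adjusted p was 0.494. The gene that rose was hmd, which encodes the hydrogen-forming methylenetetrahydromethanopterin dehydrogenase, at log2 0.78 ± 0.15 (adjusted p = 0.0243). It was not called in the fit to 6 libraries (adjusted p = 0.150, and 2.71e-05 to 0.435 over the 19 alternatives). Its level with lauric acid was near that without supplement, with a log2 fold change of 0.05 ± 0.15 between these groups (adjusted p = 0.849). The gene mcrA for the methyl-coenzyme M reductase alpha subunit had a log2 fold change of -0.45 ± 0.28 (adjusted p = 0.386), with 7708, 14699 and 6481 CPM in lauric acid replicates 7, 8 and 9 and 13124 ± 158 CPM in the DMSO control. The values were 0.31 ± 0.29 for mtrA1, 0.21 ± 0.55 for mtrA2, 0.24 ± 0.32 for mtrH, -0.58 ± 0.46 for mer, -0.21 ± 0.20 for mtd, 0.05 ± 0.11 for mch, -0.25 ± 0.17 for ftr1, -0.13 ± 0.19 for ftr2, -0.09 ± 0.19 for fwdA and -0.01 ± 0.17 for hdrA, none of them called. Of 53 hydrogenase and maturation genes, 3 rose, which were hypA, hypB and hypC, and ehaE fell by 0.40 on the log2 scale (SE 0.09, adjusted p = 0.0333). The counts were 4 and 1 adjusted over the list alone, and the camera adjusted p was 0.860. The hydrogenase genes frhA and mvhA had values of -0.02 ± 0.26 and 0.68 ± 0.23 (adjusted p = 0.969 and 0.122). For ahaA of the ATP synthase, ftsZ of cell division, dnaK and peiR the values were -0.05 ± 0.25, 0.34 ± 0.11, 0.51 ± 0.32 and -0.02 ± 0.30, and none was called. Some of these genes passed the test when 1 lauric acid culture was left out, namely mvhA at 0.93, ftr1 at -0.49 and dnaK at 0.82 without replicate 7, mcrA at -0.88 and fwdA at -0.35 without replicate 8, and mtrA1 at 0.59, mtrA2 at 0.68, mtrH at 0.57 and ftsZ at 0.43 without replicate 9.

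Further genes that rose were npdG1 at 0.55 ± 0.09, pycB of pyruvate carboxylase at 0.43 ± 0.08 and rpoL of RNA polymerase at 0.48 ± 0.11 (adjusted p = 0.0146, 0.0243 and 0.0349). The 58 tested members of the prophage, at loci mru_0256 to mru_0325, had a median log2 fold change of 0.83, and none was called by edgeR, while 4 were higher and 2 lower at an unadjusted p under 0.05 and 0 were higher and 1 lower with DESeq2. The prophage list had a camera adjusted p = 0.179.

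The DMSO control was compared with the cultures without supplement to measure the effect of the solvent addition alone. The largest named rise was that of mtrA2, named for a subunit of the methyltransferase that passes the methyl group to coenzyme M, from 614 ± 25.3 to 4602 ± 77.9 CPM (SD, n = 3 per group; log2 2.91 ± 0.59 SE, adjusted p = 0.0142), while mtrA1 had a value of 0.22 ± 0.28 (adjusted p = 0.597). The spread of the lauric acid cultures enters these SE and p. In the edgeR fit to the 6 libraries of the DMSO control and no supplement, mtrA2 had an adjusted p = 9.92e-11 and mtrA1 of 0.000687. The hybrid cluster protein gene hcp rose by 2.33 ± 0.42 (adjusted p = 0.00885), and the genes frhA, frhB1, frhD and frhG of the F420-reducing hydrogenase rose by 1.52 ± 0.27, 1.29 ± 0.28, 1.25 ± 0.27 and 1.24 ± 0.27 (adjusted p = 0.00858, 0.0175, 0.0175 and 0.0189). The tryptophan synthesis genes trpA and trpF fell, at -1.43 ± 0.14 and -1.28 ± 0.10 (adjusted p = 0.00123 and 0.000984). Also lower were nifB at -1.11 ± 0.10, hypA at -1.18 ± 0.12, hypB at -1.07 ± 0.13, the nickel transport gene nikD2 at -1.07 ± 0.14 and hmd at -0.73 ± 0.15 (adjusted p = 0.000984, 0.00123, 0.00267, 0.00374 and 0.0154). Among features with a locus ID only, mru_0431 rose by 5.07 ± 0.94 and mru_0267 of the prophage stood at -3.62 ± 1.02 (adjusted p = 0.01 and 0.0444).

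A total of 361 of 2238 genes were called, 174 higher and 187 lower, and 47 at least doubled while 34 at least halved. The 3 values of each group did not overlap at 75.5% of genes, where chance gives 10%. The fit to the 6 libraries of these groups, which leaves out the more variable lauric acid cultures, called 1643 genes, 847 higher and 796 lower, and all 361 calls were among them in the same direction. With library totals 811 genes were called higher and 15 lower, and with the median log ratio of abundant genes 241 and 158. Without no-supplement replicate 1, 2 or 3 the count was 136, 126 and 159, and without DMSO replicate 4, 5 or 6 it was 118, 108 and 113. Of the 26 named genes called here, 26 kept their call in the fit to 6 libraries, 16 with library totals, and 12 to 14 when 1 replicate was left out.

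Camera called 6 of the 20 lists. Of 58 prophage genes, 14 fell and 0 rose, and adjusted over the list alone 42 fell. Their median log2 fold change was -2.07, with a camera adjusted p = 2.75e-09 and adjusted p = 0.635 with an estimated correlation. The prophage lysis enzyme gene peiR was not called in the fit to all 9 libraries, at -0.81 ± 0.29 (adjusted p = 0.0888). It was called lower in the fit to 6 libraries (adjusted p = 0.000244) and in 3 of the 19 alternatives in all (adjusted p = 3.7e-05 to 0.680). Of 65 amino acid synthesis genes, 15 fell and 1 rose, with 16 and 2 adjusted over the list alone, a camera adjusted p = 0.000273, and adjusted p = 0.366 with an estimated correlation. Of 16 aminoacyl-tRNA synthetase genes, 5 fell, among them proS at -0.44 ± 0.07 and lysS at -0.52 ± 0.09, and 6 fell adjusted over the list alone. The camera adjusted p of this list was 0.000722, and adjusted p = 0.366 with an estimated correlation. Of 33 purine and pyrimidine synthesis genes, 8 fell, the same adjusted over the list alone, with purE2 at -0.72 ± 0.10 as an example. The list had a camera adjusted p = 0.0386, and adjusted p = 0.366 with an estimated correlation. In the fit to 6 libraries 8 of its genes rose and 16 fell, while 11 amino acid synthesis genes rose and 39 fell. Of the aminoacyl-tRNA synthetase genes 0 rose and 13 fell in that fit. With library totals the medians of the amino acid, aminoacyl-tRNA synthetase and purine lists turned positive, at 0.34, 0.29 and 0.45. The median of all genes then stood at 0.58.

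Of 18 ribosomal protein genes none was called by edgeR in the fit to 9 libraries or adjusted over the list alone, while 6 were lower at an unadjusted p under 0.05, 4 were lower with DESeq2, and 17 fell and 1 rose in the fit to 6 libraries. Their median was -0.61, with a camera adjusted p = 0.0125 and adjusted p = 0.680 with an estimated correlation. Of 34 enzymes of methane formation, mtrA2 rose and hmd fell, the same adjusted over the list alone, and in the fit to 6 libraries 30 rose and 3 fell. Their median was 0.31, with a camera adjusted p = 0.0156 for a rise and adjusted p = 0.680 with an estimated correlation. The gene mcrA had a value of 0.43 ± 0.28, mtd of 0.61 ± 0.20, mer of 0.55 ± 0.46, fwdA of 0.32 ± 0.19 and mtrH of 0.25 ± 0.32 (adjusted p = 0.308, 0.0745, 0.417, 0.255 and 0.585), none of them called in the fit to 9 libraries. In the fit to 6 libraries these 5 genes had adjusted p between 5.12e-07 and 0.000155. Of 51 genes of metal ion transport and cobalamin, 12 fell and 1 rose, with 13 and 1 adjusted over the list alone. In the fit to 6 libraries 24 of them fell and 16 rose, and the camera adjusted p was 0.0768. Of 53 hydrogenase and maturation genes, 7 rose and 3 fell, with 9 and 3 adjusted over the list alone. In the fit to 6 libraries 20 of these rose and 17 fell, and the camera adjusted p was 0.957.

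Lauric acid was also compared with no supplement, which combines the fatty acid and its solvent. The rise of nifB was 2.73-fold (log2 1.45 ± 0.10 SE, n = 3 per group, adjusted p = 0.000583), that of rbr2 3.10-fold (log2 1.63 ± 0.14, adjusted p = 0.00085), and hypB, hypA and hypC rose by 0.98 ± 0.13, 0.79 ± 0.12 and 0.76 ± 0.08 (adjusted p = 0.00506, 0.00876 and 0.00207). The genes mtrA2, hcp and frhA were higher by 3.12 ± 0.59, 2.20 ± 0.42 and 1.49 ± 0.27 (adjusted p = 0.0212, 0.021 and 0.0166), as they were in the DMSO control. In lauric acid replicate 9 they were nearer to the no-supplement level, with 1163 CPM for mtrA2 against 7955 and 6873 in replicates 7 and 8, 1755 against 6910 and 5109 for hcp, and 192 against 353 and 463 for frhA. The transcripts of deoC and fprA2 rose by 2.86 ± 0.54 and 2.14 ± 0.51 (adjusted p = 0.0211 and 0.0438), and by 1.85 and 1.15 without lauric acid replicate 9.

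Among the lower genes were moeA1 of molybdopterin synthesis at -1.001 ± 0.09, the cysteine desulfurase gene nifS at -0.84 ± 0.08, trpA at -1.13 ± 0.14 and mru_0076 at -1.39 ± 0.11 (adjusted p = 0.00142, 0.00142, 0.00437 and 0.00085). The feature mru_0431 rose by 5.20 ± 0.94 (adjusted p = 0.0185). The genes mcrA, mer and mtd had values of -0.02 ± 0.28, -0.03 ± 0.46 and 0.39 ± 0.20, and mvhA of 0.87 ± 0.23 (adjusted p = 0.975, 0.971, 0.260 and 0.0605), none of them called. Without lauric acid replicate 9, mer stood at 0.41, mtd at 0.62 and mvhA at 0.74, and without replicate 7 mvhA stood at 1.11, each past the threshold. Other genes of the fixed set, not called with all 9 libraries, passed it too. These were mtrA1 at 0.84, mtrH at 0.84, hdrA at 0.42, ftsZ at 0.23 and peiR at -1.26 without replicate 9. Leaving out replicate 7 did so for ftr1 at -0.63 and dnaK at 0.96.

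Here 158 of 2238 genes were called, 80 higher and 78 lower, with 24 at least doubled and 11 at least halved. At 25.8% of genes the values did not overlap, but the 10% that chance gives for groups of equal spread is too low a reference here too. With library totals 113 were higher and 3 lower, and without mru_2278 to mru_2285 the calls were 104 and 72. The fit to the 6 libraries compared called 10 genes, 6 higher, among them nifB and rbr2, and 4 lower, among them moeA1 and nifS. Without no-supplement replicate 1, 2 or 3 the count was 27, 25 and 46, and without lauric acid replicate 7 or 9 it was 310 and 1073. Of the 25 named genes called here, 6 kept their call in the fit to 6 libraries, 17 with library totals, and 9, 9 and 12 without no-supplement replicate 1, 2 or 3.

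Camera called 4 of the 20 lists, and 8 and 2 without lauric acid replicate 8 or 9. Of 7 genes of formate dehydrogenase and formate transport, fdhA1 and fdhB1 fell, at -0.75 ± 0.15 and -0.61 ± 0.12, and 3 fell adjusted over the list alone, with a camera adjusted p = 0.0374 and adjusted p = 0.352 with an estimated correlation. Of 5 alcohol and NADPH linked oxidoreductase genes, adh1 and npdG1 rose, by 0.78 ± 0.19 and 0.35 ± 0.09, and 4 rose adjusted over the list alone, with the same camera adjusted p and adjusted p = 0.352 with an estimated correlation. Of 58 prophage genes 2 fell, the same adjusted over the list alone, with a median of -1.02, a camera adjusted p = 2.12e-09 and adjusted p = 0.883 with an estimated correlation. Of 18 ribosomal protein genes none was called by edgeR or adjusted over the list alone, while 2 were lower at an unadjusted p under 0.05 and 0 with DESeq2. Their median was -0.40, and 0.08 with library totals, with a camera adjusted p = 0.0374 and adjusted p = 0.883 with an estimated correlation.

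The comparisons were then set beside each other gene by gene. Of the 98 genes that rose with lauric acid relative to the DMSO control, 59 had fallen in the DMSO control relative to no supplement, nifB, hypA, hypB and hmd among them, where independent lists would share 8.19. Of the 47 that fell, 20 had risen, where independent lists would share 3.65. These comparisons share the DMSO libraries, and how much overlap that brings among called genes was not tested, since draws without any effect hold almost no called genes. Across genes, which are not independent replicates, the correlation of the fold changes was -0.60 against a simulated -0.10 over 50 draws without any effect, and their covariance was -0.167 against a simulated -0.00276. The shared DMSO libraries accounted for -0.00308 of the observed covariance, while part of the excess among called genes may still come from them. The total of 79 genes with opposite calls was 6 in the fits to 6 libraries, 0 with library totals, 342, 180 and 285 without lauric acid replicate 7, 8 or 9, 6, 5 and 5 without DMSO replicate 4, 5 or 6, and 28, 18 and 27 without no-supplement replicate 1, 2 or 3. Independent lists would share 11.8 such genes in the fit to all 9 libraries, which had 4 genes called in the same direction. Without lauric acid replicate 7, 8 or 9 they would share 97.8, 38.2 and 156, and 18, 14 and 132 genes were called in the same direction. The excess of opposite calls was thus smaller in proportion without replicate 9.

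Relative to no supplement, 18 of the 98 genes that rose were also called higher and 12 of the 47 that fell were also called lower, where independent lists would share 3.50 and 1.64. These comparisons share the lauric acid libraries, and their fold changes had a correlation of 0.17 against a simulated 0.96 and a covariance of 0.0395 against a simulated 0.0949. Of the 174 genes higher and 187 lower in the DMSO control than without supplement, 44 and 51 were called in the same direction with lauric acid against no supplement, where independent lists would share 6.22 and 6.52, and 6 of the lower ones were called in the opposite direction. Those fold changes had a correlation of 0.69 against a simulated 0.18 and a covariance of 0.213 against a simulated 0.00523.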

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

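The fits without mru_2278 to mru_2285 and with a weight per group were chosen only after the results had been seen, and all other alternatives before. No paired analysis was possible because the replicate numbers 1 to 3, 4 to 6 and 7 to 9 are not shared between groups. Keeping ribosomal and transfer RNA genes was not run as an alternative, since no annotation named them. Relative log expression, upper-quartile and median-ratio scaling, both other filters, thinning, robust estimation, limma voom and the fit without mru_2278 to mru_2285 gave counts of called genes within 1.5 times those reported, at 119 to 157 for lauric acid against the DMSO control, 345 to 399 for the DMSO control against no supplement and 143 to 176 for lauric acid against no supplement. Thinning to the smallest library kept 117 of 145, 333 of 361 and 143 of 158 calls, so depth limited few of them. Among named genes, nifB, hypA and hypB rose past the threshold relative to the DMSO control in all 19 alternatives, with log2 values of 2.37 to 2.64, 1.78 to 2.07 and 1.86 to 2.16 and highest adjusted p of 0.00166, 0.012 and 0.012.

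The numbers of called genes that moved, for lauric acid against the DMSO control, the DMSO control against no supplement and lauric acid against no supplement in turn, were 338, 617 and 362 with DESeq2, 32, 1653 and 61 with a weight per group, 7, 1643 and 10 in the fits to 6 libraries, 13, 123 and 41 at an adjusted p under 0.01, and 17, 81 and 35 with at least a doubling or halving. With library totals the first 2 counts were 5 and 826. Leaving out 1 replicate gave 9 to 656, 108 to 159 and 25 to 1073. The fits to 6 libraries leave out the third group and those with a weight per group allow each group its own spread by construction. In the simulation of lauric acid against the DMSO control with unequal spread, edgeR made 1719 calls with all 9 libraries, 29.1% of them false. It made 907 with 6 libraries, 4.41% of them false, and a weight per group gave 1147, 8.46% of them false. Unequal spread thus moved the simulated counts of that comparison the same way. How much of the observed moves it explains was not tested. The stricter thresholds keep fewer genes by construction, and for the other alternatives the cause was not tested. The 79 genes with opposite calls became 194 with DESeq2, 29 with a weight per group, 6 in the fits to 6 libraries, 0 with library totals, 7 at an adjusted p under 0.01, 5 with at least a doubling or halving, and 5 to 342 without 1 replicate.

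With an estimated correlation camera called 0 lists in each comparison, and 3, 1 and 2 of 20 lists were under an unadjusted p of 0.05. With library totals it called 7 lists for lauric acid against the DMSO control, 4 of them among the 7 reported, and 3 lists for the DMSO control and 2 for lauric acid against no supplement. Without 1 replicate it called 5 to 8 lists, 5 to 7 lists and 2 to 8 lists. Without lauric acid replicate 7, 8 or 9 it called 4, 5 and 4 of the 7 lists reported against the DMSO control again, with 0, 2 and 1 lists called lower, and 3, 4 and 1 of the 4 reported against no supplement. By fry, which tests whether genes of a list move on balance one way and not whether they differ from other genes, 9, 6 and 3 lists were called.

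Some named genes changed sign, and the cause was not tested. For lauric acid against the DMSO control, mtrA2 stood at -0.13 with library totals, -0.23 with limma voom and -0.21 with a weight per group, mtrH at -0.021 with library totals, mch at -0.017 with upper-quartile factors, -0.19 with library totals and -0.010 with the median log ratio, hdrA at 0.0016 with relative log expression factors, 0.00075 without mru_2278 to mru_2285 and 0.0016 with DESeq2, and peiR at 0.038 after thinning. For the DMSO control against no supplement with library totals, mch stood at 0.49, ftr1 at 0.44, ahaA at 0.30, ftsZ at 0.36, proS at 0.14, lysS at 0.059 and fdhA1 at 0.057, of which proS, lysS and fdhA1 had been called as lower. For lauric acid against no supplement with library totals, mcrA stood at 0.36, mer at 0.21, mch at 0.30, ftr2 at 0.29 and ahaA at 0.11, and without mru_2278 to mru_2285 mcrA stood at 0.0075 and ftr2 at 0.0087.

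Without 1 replicate, values relative to the DMSO control ranged from -0.015 to 0.59 for mtrA1, -0.20 to 0.68 for mtrA2, -0.039 to 0.57 for mtrH, -0.075 to 0.13 for mch, -0.34 to 0.063 for ftr2, -0.35 to 0.035 for fwdA, -0.32 to 0.25 for frhA, -0.12 to 0.14 for hdrA, -0.29 to 0.22 for ahaA and -0.48 to 0.25 for peiR. Relative to no supplement they ranged from -0.43 to 0.22 for mcrA, -0.48 to 0.41 for mer, -0.069 to 0.24 for hmd, -0.17 to 0.063 for mch, -0.23 to 0.20 for ftr2 and -0.0054 to 0.38 for fwdA with lauric acid.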

Other observations

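The tests of narrower gene lists, of a swapped culture, of an unexposed culture that varied like the others, of the difference between the DMSO control and no supplement and of the opposed fold changes were chosen only after the results had been seen. Tryptophan synthesis, nickel transport and hydrogenase maturation stood out among 14 narrower lists. Since these lists were written with the gene results known, neither their calls over the list alone nor their camera p are independent evidence. All 8 tested tryptophan synthesis genes fell in the DMSO control relative to no supplement, with a median log2 fold change of -0.91, a camera adjusted p = 3.7e-09 and adjusted p = 0.226 with an estimated correlation. With lauric acid 5 of them rose relative to the DMSO control, trpE at 0.45 ± 0.08 SE and trpB2 at 0.66 ± 0.13 among them, and 6 were still lower than without supplement (camera adjusted p = 3.21e-06 and 2.91e-06; adjusted p = 0.208 and 0.243 with an estimated correlation). Of 10 nickel transport genes, 8 fell in the DMSO control and 5 rose with lauric acid relative to it (camera adjusted p = 3.6e-06 and 1.21e-07; adjusted p = 0.243 and 0.208 with an estimated correlation). Relative to no supplement none of the 10 was called by edgeR with lauric acid, while 1 was higher and 1 lower at an unadjusted p under 0.05. Of 7 hydrogenase maturation genes, hypA, hypB and hypC rose with lauric acid against either other group (camera adjusted p = 0.000242 and 0.00202; adjusted p = 0.127 and 0.204 with an estimated correlation).

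The membrane-bound hydrogenases Eha and Ehb, which couple hydrogen to ferredoxin reduction, differed in which comparison they were called. Of 19 Eha genes 1 fell with lauric acid relative to the DMSO control, with a median of -0.20, a camera adjusted p = 0.000899 and adjusted p = 0.735 with an estimated correlation. Of 17 Ehb genes 1 fell in the DMSO control and 1 with lauric acid relative to no supplement, with medians of -0.18 and -0.20, which were 0.41 and 0.21 with library totals. Their camera adjusted p were 0.0355 and 0.00387, and adjusted p = 0.624 and 0.615 with an estimated correlation. The difference between Eha and Ehb was not tested. The other 9 narrower lists were called by camera in no comparison.

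Lauric acid replicate 9 lay at 0.118 on an axis over 1643 genes that runs from 0 for no supplement to 1 for the DMSO control, while lauric acid replicates 7 and 8 lay at 0.965 and 0.852. Replicate 9 was itself the smallest library, so thinning left its counts as they were, and its position of 0.121 after thinning says nothing about depth. Thinned to that depth, replicates 7 and 8 stayed at 0.958 and 0.827, which argues against lower depth as the cause. The position of replicate 9 stayed at 0.0993 without mru_2278 to mru_2285, which argues against a few abundant features. A swap with a culture of the other groups was argued against by a smallest root mean square log2 difference of 0.554 between replicate 9 and those 6 cultures. Their largest difference within a group was 0.244, which also argues against an unexposed culture that varied like them. Replicate 9 lay outside all 6 at 70.8% of the 380 genes that replicates 7 and 8 set apart from both other groups. For 1 of the 6 beside the other 5 this share was at most 45.0%. The 380 genes were chosen in a fit that used the 6 cultures but not replicate 9. That choice can widen the difference between the shares, so no conclusion is drawn from it. An unexposed culture that differed in another way cannot be told apart from an exposed one, since replicate 9 lay beyond all 6 in the direction of replicates 7 and 8 at 27.1% of these genes and in the opposite one at 43.7%, where chance gives 14.3% each, although by at least a doubling it did so at 14 and 3 genes, with nifB at 556 CPM against at most 208 and fprA2 at 7457 CPM against at most 852. A response of this culture that differed in time or strength stays open as an untested biological explanation.

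Many genes differed between the DMSO control and no supplement although the cultures within each group were alike. Of the 361 calls, 355 were found again without mru_2278 to mru_2285 and 333 after thinning to the smallest library, which argues against abundant features and depth as the whole cause. Values did not overlap at 75.5% of genes, where chance gives 10%, and an effect of the solvent cannot be told apart from bottles that were grown or handled as a group, because the labels describe a single set of bottles.

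The changes with lauric acid relative to the DMSO control ran opposite to those of the DMSO control relative to no supplement, with a covariance over genes of -0.167. The shared DMSO libraries account for -0.00308 of it, so they are argued against as the whole cause. A displacement of the DMSO cultures alone is argued against for lauric acid replicates 7 and 8, since the lower of their axis positions was 0.852 and not near 0. Most of the pattern rested on lauric acid replicate 9, which taken alone gave -0.324, and the covariance was -0.0324 without it. Replicates 7 and 8 taken alone gave -0.0164 and -0.0568, and a DMSO culture beside the other 2 gave -0.00843 at the lowest. That reference is too narrow, since DMSO cultures differed among themselves by a root mean square of 0.129 to 0.143. Replicates 7 and 8 differed from them by 0.511 to 0.542. Whether replicate 9 was the whole cause is therefore not decided. An effect of lauric acid on the same genes stays open as an untested biological explanation.

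There are 10 splits of 6 cultures into 3 and 3, so the share of splits with a count as large as the real one cannot go under 0.05, and it was 1 of 10 in each comparison. The real counts by edgeR were 145, 361 and 158 genes, and the highest of the other splits was 0 in each, with at most 220, 4 and 456 genes at an unadjusted p under 0.05.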
